A study of Homo sapiens with 38 samples.

How the data were processed

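Gene counts of 38 bulk RNA-seq libraries were used. The counts were deposited by the authors as tables of unnormalized integers per gene symbol, 1 table for sets 1 to 3 and 1 for set 4. Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned to hg38 with STAR 2.7.4a and counted with featureCounts 2.0.1. Per the labels the libraries are of H9-derived cells, and the groups and replicate numbers were read from the labels. The annotation and the strand used for counting were not stated. Of 59368 symbols, 55822 matched GENCODE 29, which gave the positions of named genes, and 2 list members were matched to other symbols (TPRX2P for TPRX2 and H3.Y for H3Y1). Every value was a whole number, totals ran from 24796986 to 45422011 counts per library, and a gene at 0 over a group was given a floor of 3 counts over the group.

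Each set was fitted alone with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, scaled by TMM and fitted with group means by glmQLFit, and contrasts were tested with edgeR's quasi-likelihood test. Benjamini-Hochberg adjustment ran over all genes tested in a contrast, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was its size over the square root of the F statistic. CPM in the text are TMM-scaled, except for the levels of OTX2 in the data description, GFP and the mitochondrial share, which use the plain library total. The 15 comparisons were naive against primed and TLSC against naive WT cells in sets 1 and 2, OTX2-KO against WT in each state of set 1, OTX2-OE against WT in each state of set 2, 4 pairs of TLSC groups in set 3 and GFP against ne libraries in set 4. Another 4 contrasts tested interactions, and 7 overlaps set calls of comparisons that share no library against n1 × n2 / N, with Fisher's exact test.

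There were 20 gene lists, fixed beforehand: 8-cell embryo genes, DUX4 target genes, naive, primed and shared pluripotency genes, trophoblast, hypoblast, amnion, neuroectoderm, mesendoderm, oocyte and germ cell, fibroblast, and endothelial and blood genes, targets of Nodal and TGF-beta, of FGF and ERK and of p53, the DNA methylation machinery, stress response genes, cell cycle genes and mitochondrially encoded genes. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a contrast and at least 5 members tested.

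Genes were named by a rule fixed beforehand. It took OTX2 and DUX4, the 6 rising and the 6 falling called genes with the largest log2 fold change at a mean of at least 5 CPM, up to 3 rising and 3 falling called members of each list at a mean of at least 1 CPM or the 2 members with the highest mean where none was called, and a fixed set of key genes whatever their result. Identifiers without a symbol, clone-based names, LINC, MT- and small RNA genes and pseudogene names were among those left out of the genes chosen by fold. The rule named 1961 gene results, each run under the alternatives that apply to it, of which the text names a part. Fits of only 2 groups cover neither interactions nor set 4 and leave out genes that fail their filter, and DESeq2 gave no adjusted p for some results.

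Alternatives were DESeq2 1.42.0, RLE factors in place of TMM, no low-count filter, a call that also needs a log2 fold change of at least 1 in size, the replicate number as a block, a fit of only the 2 groups compared, and each library left out in turn. With 1 library left in a group, that library is assumed to vary like the other groups. A crossed replicate block and a fit without replicate 3 of both groups of set 4 were chosen after seeing the data. No block was used in the calls reported. In set 4, 10 splits of the 6 libraries were fitted too.

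The procedure was tested on simulated data with the depth, the mean level per gene and the trended spread of the sets of 4 comparisons. At changes of 1.5, 2 and 4-fold it recovered 64.4%, 87.3% and 97.9% (47 of 73, 69 of 79 and 47 of 48) for OTX2-KO in primed cells, 80%, 82.9% and 100% (60 of 75, 63 of 76 and 49 of 49) for OTX2-OE in TLSC, 54.7%, 73.7% and 98% (41 of 75, 56 of 76 and 48 of 49) for OTX2-KO in TLSC of set 3 and 14.3%, 85% and 94.7% (9 of 63, 68 of 80 and 54 of 57) for GFP against ne libraries. Genes called without a simulated change numbered 11, 9, 2 and 6, among 23439, 23027, 20825 and 21436 simulated genes. No library was left out of the calls reported. The GFP and tdtomato entries of set 4 were kept out of library totals and tests. Figures were drawn with matplotlib 3.10.9.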

Results

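RNA abundance was measured by bulk RNA sequencing in 38 libraries from cells derived from H9, an established line of human embryonic stem cells. The libraries formed 18 groups in 4 sets. Set 1 held primed, naive (4CL medium) and TLSC (me4CL medium, totipotent-like) cultures of WT cells and of cells labelled OTX2-KO. Set 2 held the same 3 states of WT cells and of cells labelled OTX2-OE. The labels name the primed libraries of set 2 ndox (WT) and pdox (OTX2-OE), read here as without and with doxycycline, and do not state doxycycline for the others. Set 3 held TLSC of WT, OTX2-KO, DUX4-OE and DUX4-OE OTX2-KO cells, and set 4 held GFP and ne libraries of OTX2-KO cells in me4CL. Groups had n = 2 libraries in sets 1 to 3 and n = 3 in set 4. Values are TMM-scaled CPM as mean ± SD, the group named first standing first, and the number of libraries is that of the group unless given. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test, with log2FC for the log2 fold change. Lists, fixed beforehand, were said to rise or fall by camera with a preset correlation, and each such call is followed by its adjusted p with an estimated correlation, written estimated. Counts adjusted over the list alone are given where they differed from those over all genes. The 8-cell embryo and DUX4 target lists share members such as DUXA and ZSCAN4, so their results are not independent. The labels do not state that replicates were separate cultures, so each p measures the spread between these libraries, and floors for genes with 0 counts cover counting error only. Among called results of named genes with n = 2, 1358 of 1364 had all libraries of 1 group above all of the other, an order that random ranks would give in 33.3%, and with n = 3 it was 90 of 90 (10%). Calls select for this order, so it is no separate test. The exceptions were CDX2 between naive and primed cells in sets 1 and 2, RMRP between TLSC and naive WT cells and with OTX2-KO in naive cells of set 1, MT-ND5 with OTX2-KO in TLSC of set 1 and MT-CO3 with OTX2-KO in TLSC of set 3.

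OTX2, a homeodomain transcription factor of the epiblast and anterior neural plate (chromosome 14, 56799905 to 56810479, GRCh38), was counted in all libraries. As CPM of the unscaled library total it stood at 51.85 ± 2.022 in primed libraries labelled OTX2-KO and at 17.56 ± 0.7495 in primed WT (SD, n = 2). In TLSC of set 1 the values were 11.62 ± 0.9475 and 6.71 ± 0.7212, in naive cells 11.86 ± 0.1768 and 13.33 ± 1.697, and in TLSC of set 3 6.075 ± 0.8132 and 5.665 ± 0.7707. Counts per gene cannot show a frameshift or the loss of an exon, so they do not check the knockout. With OTX2-OE, OTX2 stood at 25.46 ± 1.464 against 20.69 ± 2.164 in primed cells, 36.11 ± 0.3253 against 24.7 ± 2.913 in naive cells and 220 ± 15.46 against 6.61 ± 0.1838 in TLSC. DUX4 (chromosome 4, 190173774 to 190185942), the double homeobox factor of zygotic genome activation, lies in repeats, and DUX4 with its DUX4L copies summed to between 1 and 155 counts per library. In set 3 the sums were 41 and 18 in WT, 17 and 35 in DUX4-OE, 28 and 23 in OTX2-KO and 64 and 68 in DUX4-OE OTX2-KO libraries, with DUX4 itself at 0, so DUX4-OE rests on the label and no rise of counted DUX4 RNA was seen in DUX4-OE against WT libraries. Counts of the MBD3L, PRAMEF, RFPL4, TRIM43 and DUX4 families are uncertain between near-identical copies, and the strand of the counts was not stated, so overlapping and antisense genes are uncertain too.

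**Figure D1:**
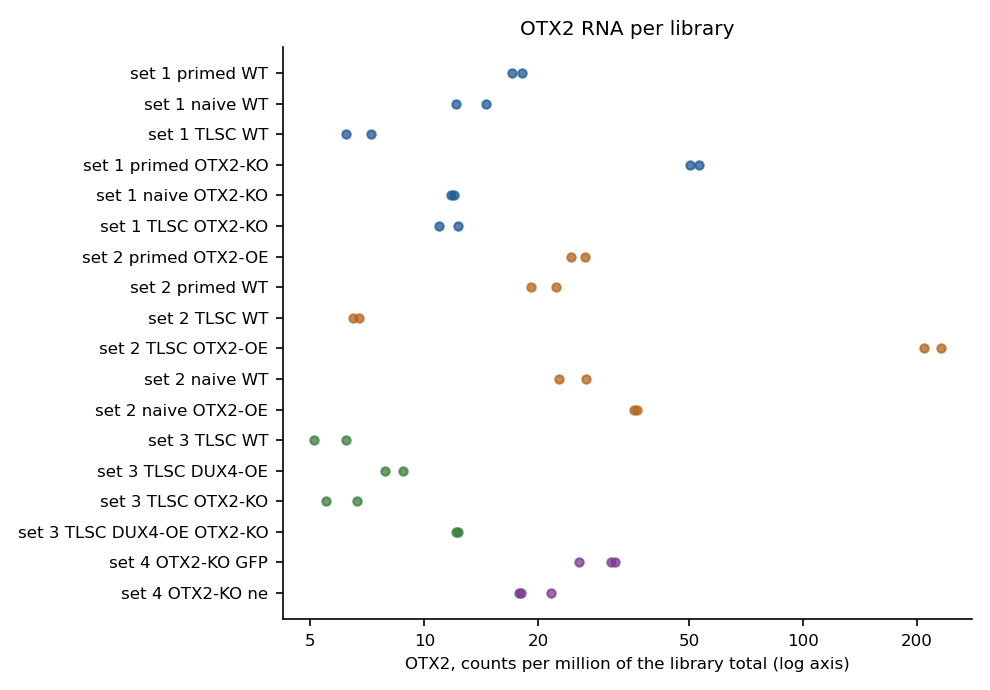
OTX2 RNA in each of the 38 libraries as CPM of the library total (log axis), 1 point per library, 1 line per group, coloured by set. The primed OTX2-KO libraries average 51.85 CPM and the TLSC OTX2-OE libraries 220 CPM.

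Naive and primed WT cells were compared in sets 1 and 2 to describe the starting states. Naive pluripotency genes rose in naive cells of set 1 (22 rose and 3 fell of 27, camera adjusted p = 5.2e-07, estimated 0.13). The rise was found in set 2 as well (24 rose and 1 fell of 26, camera adjusted p = 4.5e-09, estimated 0.059). They included FGF4 (426 ± 17 against 1.66 ± 0.2 CPM, log2FC 8, adjusted p = 1.02e-21), DNMT3L (63.8 ± 5.6 against 0.226 ± 0.057 CPM, log2FC 8.12, adjusted p = 2.35e-20), a cofactor of de novo DNA methylation, and DPPA5 (195 ± 4.1 against 0.889 ± 0.24 CPM, log2FC 7.77, adjusted p = 1.21e-21), all in set 1, with log2FC of 7.79, 6.52 and 6.52 in set 2. Primed pluripotency genes fell (3 rose and 20 fell of 24, camera adjusted p = 1.3e-06, estimated 0.13) in set 1. They also fell in set 2 (5 rose and 19 fell of 24, camera adjusted p = 2.6e-06, estimated 0.035). Set 1 had lower SFRP2 (10.2 ± 1.5 against 404 ± 16 CPM, log2FC −5.31, adjusted p = 1.02e-21), a secreted WNT modulator, and ZIC2 (6.67 ± 1.3 against 158 ± 4 CPM, log2FC −4.57, adjusted p = 1.95e-18). FGF and ERK target genes fell too in set 1 (0 rose and 14 fell of 16, camera adjusted p = 1.3e-06, estimated 0.027). In set 2 they fell as well (0 rose and 15 fell of 16, 1 and 15 adjusted over the list alone, camera adjusted p = 1.8e-09, estimated 0.0088). Members included SPRY4 (1.05 ± 0.47 against 326 ± 5.2 CPM, log2FC −8.29, adjusted p = 1.36e-22), an inhibitor of receptor tyrosine kinase signalling, and DUSP6 (0.41 ± 0.072 against 279 ± 16 CPM, log2FC −9.4, adjusted p = 2.66e-21), an ERK phosphatase.

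Genes of the 8-cell embryo were not called as a list (10 rose and 2 fell of 35, camera adjusted p = 0.2) in set 1 and were not called in set 2 either (7 rose and 1 fell of 30, camera adjusted p = 0.32). Those that rose included KLF17 (10.8 ± 1.5 against 0.16 ± 0.23 CPM, log2FC 6.06, adjusted p = 5.14e-14) and DPPA3 (26.8 ± 0.62 against 0.465 ± 0.28 CPM, log2FC 5.84, adjusted p = 1.11e-18). Cell cycle genes fell (1 rose and 13 fell of 19, camera adjusted p = 6e-04, estimated 0.31) in set 2, with CCND1 (24.8 ± 1.8 against 203 ± 7.8 CPM, log2FC −3.03, adjusted p = 9.42e-18), the G1 cyclin. OTX2 was not called in set 1 (15.7 ± 1.2 against 16.4 ± 0.96 CPM) and rose in set 2 (25.5 ± 3.1 against 21.1 ± 2.3 CPM, log2FC 0.27, SE 0.1, adjusted p = 0.0214). In set 1, 7696 genes were higher and 7607 lower of 25063 tested, 4794 and 5070 of them by at least 2-fold. In set 2, 6405 genes were higher and 6583 lower of 24753 tested, 3329 and 3020 of them by at least 2-fold. This balance turned with RLE factors (6529 higher, 6464 lower) and DESeq2 (6216 higher, 6082 lower). Mitochondrially encoded genes took 10.16% ± 1.782 of counts in naive and 6.65% ± 0.1131 in primed WT cells of set 1 (SD, n = 2). OTX2 was not called without primed WT replicate 2 or naive WT replicate 1 in set 2.

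TLSC and naive WT cells were compared to describe the step into me4CL. The 8-cell embryo genes rose in set 1 (27 rose and 0 fell of 35, camera adjusted p = 2.3e-10, estimated 0.017). They rose in set 2 too (29 rose and 0 fell of 30, camera adjusted p = 1.6e-14, estimated 0.0068). Homeobox genes of the 8-cell stage were among them. TPRX1 (166 ± 18 against 1.5 ± 0.27 CPM, log2FC 6.78, adjusted p = 1.96e-20) rose in set 1, and its log2FC was 5.64 in set 2. DUXA, with 0 counts in naive cells, stood at 4.82 ± 0.063 against 0 ± 0 CPM in set 1, at least 86.8-fold higher, and at 3.51 ± 0.62 against 0 ± 0 CPM in set 2, at least 80.1-fold higher. ZSCAN4 (2.57 ± 0.19 against 0.189 ± 0.17 CPM, log2FC 3.76, adjusted p = 5.56e-09), a zinc finger gene of cleavage-stage embryos, KLF17 (100 ± 10 against 10.8 ± 1.5 CPM, log2FC 3.21, adjusted p = 5.38e-15) and DPPA3 (119 ± 1.2 against 26.8 ± 0.62 CPM, log2FC 2.14, adjusted p = 3.18e-15) rose in set 1. DUX4 target genes rose in set 1 (17 rose and 0 fell of 23, camera adjusted p = 2.8e-07, estimated 0.028). In set 2 these rose too (18 rose and 0 fell of 18, camera adjusted p = 7.1e-10, estimated 0.039). Shared pluripotency genes fell in set 1 (1 rose and 14 fell of 15, camera adjusted p = 2.8e-07, estimated 0.13). Set 2 showed a fall as well (1 rose and 12 fell of 15, camera adjusted p = 2.3e-06, estimated 0.039). Genes that fell in set 1 included POU5F1 (1170 ± 5.3 against 2470 ± 280 CPM, log2FC −1.08, adjusted p = 1.45e-11), SOX2 (81.7 ± 9.1 against 449 ± 40 CPM, log2FC −2.46, adjusted p = 3.28e-16) and TDGF1 (219 ± 34 against 1320 ± 16 CPM, log2FC −2.59, adjusted p = 2.53e-17), a Nodal co-receptor. OTX2 fell in both sets (6.46 ± 0.76 against 15.7 ± 1.2 CPM, log2FC −1.28, SE 0.13, adjusted p = 7.38e-09 in set 1; 6.65 ± 0.2 against 25.5 ± 3.1 CPM, log2FC −1.94, SE 0.11, adjusted p = 1.19e-12 in set 2).

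Lists of other cell types rose as well in TLSC. In set 2 these were trophoblast (19 rose and 1 fell of 22, camera adjusted p = 1.3e-05, estimated 0.039), hypoblast (13 rose and 2 fell of 17, camera adjusted p = 0.0064, estimated 0.055), amnion (10 rose and 2 fell of 13, camera adjusted p = 0.007, estimated 0.055), neuroectoderm (18 rose and 3 fell of 24, 18 and 4 adjusted over the list alone, camera adjusted p = 0.0077, estimated 0.052), fibroblast (12 rose and 0 fell of 14, camera adjusted p = 0.00094, estimated 0.051) and endothelial and blood genes (5 rose and 0 fell of 8, camera adjusted p = 0.05 after rounding up, estimated 0.12). In set 1 they were trophoblast (17 rose and 0 fell of 22, camera adjusted p = 0.00026, estimated 0.13), hypoblast (12 rose and 2 fell of 18, camera adjusted p = 0.012, estimated 0.14), amnion (8 rose and 2 fell of 11, camera adjusted p = 0.04, estimated 0.15), neuroectoderm (13 rose and 3 fell of 22, 14 and 3 adjusted over the list alone, camera adjusted p = 0.0052, estimated 0.13), fibroblast (11 rose and 0 fell of 14, camera adjusted p = 5e-05, estimated 0.06) and endothelial and blood genes (6 rose and 0 fell of 10, camera adjusted p = 0.024, estimated 0.13). Mesendoderm genes rose (14 rose and 3 fell of 20, 15 and 3 adjusted over the list alone, camera adjusted p = 0.01, estimated 0.056) in set 2 and were not called as a list (11 rose and 4 fell of 19, camera adjusted p = 0.059) in set 1. Trophoblast members included TFAP2A (13.3 ± 3.8 against 0.104 ± 0.068 CPM, log2FC 6.97, adjusted p = 2.91e-12) in set 2. Members at few counts in naive cells were among these, such as GATA3 (10.9 ± 2.2 against 0.0305 ± 0.043 CPM, adjusted p = 4.97e-11) of trophoblast and amnion in set 2 and GATA6 (6.35 ± 0.29 against 0 ± 0 CPM, at least 114-fold higher, adjusted p = 2.86e-11) of the hypoblast in set 1. Oocyte and germ cell genes rose (21 rose and 2 fell of 26, camera adjusted p = 5e-05, estimated 0.04) in set 1 and in set 2 (20 rose and 2 fell of 25, camera adjusted p = 0.0043, estimated 0.047), with MAEL (87.8 ± 2.9 against 4.84 ± 0.045 CPM, log2FC 4.18, adjusted p = 4.08e-19), a factor of the piRNA pathway, in set 1. Stress response genes rose (15 rose and 1 fell of 17, camera adjusted p = 8.9e-05, estimated 0.13), with HMOX1 (95.9 ± 12 against 19 ± 0.91 CPM, log2FC 2.34, adjusted p = 6.13e-15), in set 1 and in set 2 (15 rose and 1 fell of 17, camera adjusted p = 1e-05, estimated 0.056). Mitochondrially encoded genes fell (0 rose and 13 fell of 13, camera adjusted p = 0.00012, estimated 0.33) in set 1 and in set 2 (1 rose and 12 fell of 13, camera adjusted p = 0.00013, estimated 0.21). In set 1, 7416 genes were higher and 6179 lower of 25063 tested, 5120 and 1948 of them by at least 2-fold. In set 2, 8009 genes were higher and 6637 lower of 24753 tested, 5430 and 2336 of them by at least 2-fold. Of genes tested in both sets, 8846 changed in the same direction against 4070 from n1 × n2 / N, and 1162 in opposite directions (Fisher exact p under the smallest value that double precision holds; Pearson 0.6 and Spearman 0.542 across genes, which are not independent replicates). The endothelial and blood genes were not called with RLE factors (adjusted p = 0.059) in set 2.

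**Figure D2:**
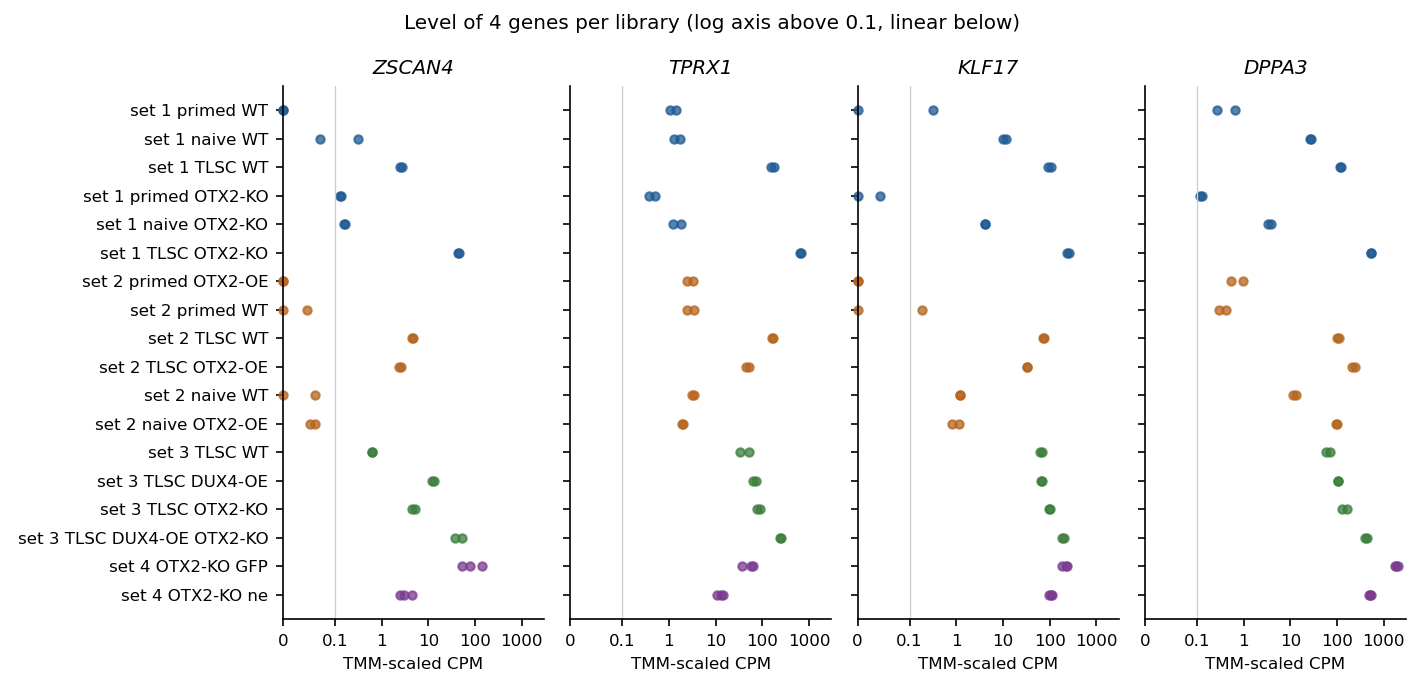
TMM-scaled CPM of ZSCAN4, TPRX1, KLF17 and DPPA3 in each library (1 point per library, 1 line per group, coloured by set; axis linear below 0.1 and log above). TPRX1 averages 658 CPM in TLSC OTX2-KO of set 1 and 166 CPM in TLSC WT.

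OTX2-KO and WT primed cells of set 1 were compared to ask what the knockout changed before the switch of medium. p53 target genes rose (16 rose and 0 fell of 18, 17 and 0 adjusted over the list alone, camera adjusted p = 5.3e-20, estimated 0.012). GDF15 (74.6 ± 1.7 against 10.8 ± 0.96 CPM, log2FC 2.79, SE 0.09, adjusted p = 8.01e-16), a stress-induced cytokine, CDKN1A (96.4 ± 2.4 against 27.3 ± 0.21 CPM, log2FC 1.82, adjusted p = 1.47e-13), the p21 inhibitor of cell cycle kinases, and BTG2 (40.8 ± 1.8 against 11.8 ± 0.23 CPM, log2FC 1.79, adjusted p = 1.8e-09), an antiproliferative gene, rose most among members of the list over 1 CPM. Stress response genes rose (11 rose and 0 fell of 17, 12 and 1 adjusted over the list alone, camera adjusted p = 5.9e-08, estimated 0.19). Members included DDIT3 (6.67 ± 0.64 against 1.61 ± 0.14 CPM, log2FC 2.05, adjusted p = 1.19e-08) and PPP1R15A (27.5 ± 1.6 against 15.3 ± 2.2 CPM, log2FC 0.85, adjusted p = 1.75e-06). GDA (0.0457 ± 0.065 against 13.1 ± 0.29 CPM, log2FC −8.1, adjusted p = 1.22e-11), guanine deaminase, fell most of the named genes. The naive pluripotency genes (3 rose and 4 fell of 27, camera adjusted p = 0.57) and the 8-cell embryo genes (1 rose and 4 fell of 35, camera adjusted p = 0.57) were not called as lists. SOX2 (241 ± 3.8 against 214 ± 11 CPM, adjusted p = 0.193) and NANOG (131 ± 4.7 against 111 ± 0.76 CPM, adjusted p = 0.0527) were not called, and POU5F1 (1480 ± 28 against 1210 ± 55 CPM, log2FC 0.29, adjusted p = 0.00853) rose. OTX2 rose (51 ± 1.8 against 16.4 ± 0.96 CPM, log2FC 1.64, SE 0.11, adjusted p = 1.8e-09). In all, 2145 genes were higher and 1822 lower of 25063 tested, 245 and 759 of them by at least 2-fold, with 7510 genes called when only the 2 groups were fitted. This balance turned with RLE factors (1890 higher, 1936 lower). The number called, 3967, became 1690 without primed WT replicate 2, 2010 without primed OTX2-KO replicate 1 and 1872 without primed OTX2-KO replicate 2. POU5F1 was not called without primed WT replicate 2 or primed OTX2-KO replicate 2. SOX2 and NANOG were called with only the 2 groups compared (adjusted p = 0.00099 and 7.34e-05).

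The same comparison was made in naive cells of set 1. p53 target genes fell (1 rose and 14 fell of 18, camera adjusted p = 3.3e-05, estimated 0.16). Among them were SESN1 (60 ± 2.9 against 135 ± 7.1 CPM, log2FC −1.17, SE 0.08, adjusted p = 4.01e-10), a sestrin, ZMAT3 (38 ± 3.5 against 70 ± 3.6 CPM, log2FC −0.88, adjusted p = 3.1e-08) and CDKN1A (60.3 ± 1.3 against 106 ± 5.7 CPM, log2FC −0.81, adjusted p = 7.68e-09). Several genes of the naive state and the early embryo fell: DPPA3 (3.57 ± 0.45 against 26.8 ± 0.62 CPM, log2FC −2.91, adjusted p = 5.67e-14), KLF17 (4.13 ± 0.092 against 10.8 ± 1.5 CPM, log2FC −1.39, adjusted p = 1.08e-06), SUSD2 (11.6 ± 1 against 35.4 ± 1.3 CPM, log2FC −1.61, adjusted p = 2.4e-11), a surface marker of naive cells, and TBX3 (0.444 ± 0.12 against 7.04 ± 0.4 CPM, log2FC −3.99, adjusted p = 4.86e-11). Others rose, such as TFCP2L1 (13.2 ± 0.56 against 6.94 ± 0.43 CPM, log2FC 0.92, adjusted p = 1.27e-05) and KHDC3L (21 ± 1.3 against 8.51 ± 0.87 CPM, log2FC 1.3, adjusted p = 3.64e-07). The list as a whole was not called (8 rose and 10 fell of 27, 9 and 10 adjusted over the list alone, camera adjusted p = 0.31). Primed pluripotency genes fell (2 rose and 13 fell of 24, 4 and 13 adjusted over the list alone, camera adjusted p = 0.013, estimated 0.65). Members included ZIC2 (1.26 ± 0.54 against 6.67 ± 1.3 CPM, log2FC −2.42, adjusted p = 5.29e-09). POU5F1 (1450 ± 62 against 2470 ± 280 CPM, log2FC −0.77, adjusted p = 2.86e-08) fell. In turn, the 8-cell embryo genes were not called as a list (2 rose and 5 fell of 35, 1 and 5 adjusted over the list alone, camera adjusted p = 0.67). TPRX1 stood at 1.49 ± 0.4 against 1.5 ± 0.27 CPM (adjusted p = 0.984). HTR7 (43.4 ± 2 against 1.22 ± 0.2 CPM, log2FC 5.15, adjusted p = 9.41e-16), a serotonin receptor gene, rose most of the named genes. Mitochondrially encoded genes rose (10 rose and 0 fell of 13, 12 and 0 adjusted over the list alone, camera adjusted p = 0.0033, estimated 0.8). They took 14.76% ± 0.601 of counts in OTX2-KO against 10.16% ± 1.782 in WT (SD, n = 2). OTX2 fell (12.4 ± 0.064 against 15.7 ± 1.2 CPM, log2FC −0.34, SE 0.12, adjusted p = 0.0279). In all, 4619 genes were higher and 4647 lower of 25063 tested, 1796 and 1048 of them by at least 2-fold. The primed pluripotency genes were not called without naive WT replicate 2 or naive OTX2-KO replicate 1. OTX2 was not called without naive WT replicate 1 or naive OTX2-KO replicate 1 or 2. Nor was it called with no low-count filter (adjusted p = 0.11) or only the 2 groups compared (0.0516).

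The OTX2-KO effect in naive cells minus that in primed cells was tested as an interaction, with log2 differences in parentheses. The p53 target genes had negative differences (0 positive and 16 negative of 18, camera adjusted p = 8.6e-14, estimated 0.033). GDF15 (−3.29, SE 0.12, adjusted p = 1.46e-14), CDKN1A (−2.63, SE 0.1, adjusted p = 5.92e-14) and BTG2 (−2.54, SE 0.17, adjusted p = 4.63e-10) had the most negative differences of members over 1 CPM. SUSD2 (−2.05, SE 0.15, adjusted p = 1.84e-09) and POU5F1 (−1.06, SE 0.1, adjusted p = 9.44e-08) rose in primed and fell in naive cells. Shared pluripotency genes had negative differences (1 positive and 9 negative of 15, camera adjusted p = 0.0022, estimated 0.57). Here the 8-cell embryo genes were not called as a list (1 positive and 3 negative of 35, camera adjusted p = 0.95). In all, 3549 differences were positive and 3878 negative of 25063 genes tested, 1827 and 840 of them at least 2-fold.

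**Figure D3:**
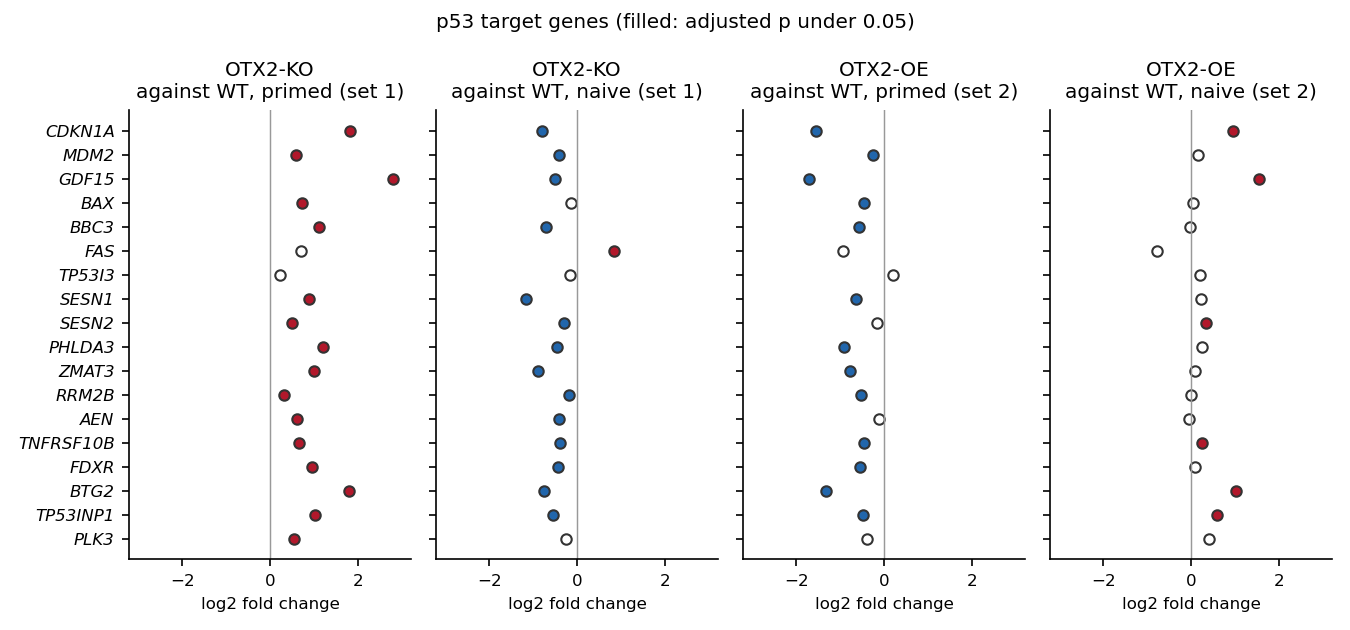
Log2 fold changes of the 18 p53 target genes with OTX2-KO (set 1) and OTX2-OE (set 2) against WT in primed and naive cells, 1 point per gene, filled red (higher) or blue (lower) where adjusted p was under 0.05 and open otherwise. CDKN1A, GDF15 and BTG2 lie right of 0 in primed OTX2-KO and naive OTX2-OE and left of 0 in naive OTX2-KO and primed OTX2-OE.

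In TLSC of set 1, OTX2-KO and WT cells were compared to ask whether the knockout moved genes of the 8-cell stage. Genes of the 8-cell embryo rose (34 rose and 0 fell of 35, camera adjusted p = 2.8e-19, estimated 0.0023). TPRX1 (658 ± 28 against 166 ± 18 CPM, log2FC 1.99, SE 0.09, adjusted p = 7.62e-14), DUXA (58.4 ± 2.1 against 4.82 ± 0.063 CPM, log2FC 3.6, adjusted p = 1.24e-12) and LEUTX (26 ± 2.4 against 2 ± 0.11 CPM, log2FC 3.7, adjusted p = 2.76e-10), homeobox genes active at genome activation, were among them, with KLF17 (246 ± 13 against 100 ± 10 CPM, log2FC 1.29, adjusted p = 8.93e-09) and DPPA3 (535 ± 6 against 119 ± 1.2 CPM, log2FC 2.17, adjusted p = 1.04e-14). DUX4 target genes rose (23 rose and 0 fell of 23, camera adjusted p = 6.8e-18, estimated 0.0023). Members included ZSCAN4 (43.6 ± 1.5 against 2.57 ± 0.19 CPM, log2FC 4.09, adjusted p = 2.38e-13) and MBD3L2 (17.7 ± 3.1 against 0.395 ± 0.037 CPM, log2FC 5.48, adjusted p = 2.03e-11). Naive pluripotency genes rose (19 rose and 4 fell of 27, camera adjusted p = 0.041, estimated 0.42), with SUSD2 (384 ± 32 against 548 ± 32 CPM, log2FC −0.51, adjusted p = 1.17e-05) and DPPA5 (209 ± 9.2 against 288 ± 18 CPM, log2FC −0.46, adjusted p = 0.000181) among those that fell. Stress response genes rose (12 rose and 2 fell of 17, camera adjusted p = 7.9e-05, estimated 0.21). Among them was HSPA1A (411 ± 23 against 106 ± 5 CPM, log2FC 1.95, adjusted p = 1.56e-14), an inducible HSP70. POU5F1 (821 ± 6.3 against 1170 ± 5.3 CPM, log2FC −0.51, adjusted p = 7.91e-06) fell. Trophoblast (7 rose and 2 fell of 22, 8 and 2 adjusted over the list alone, camera adjusted p = 0.055), hypoblast (6 rose and 5 fell of 18, camera adjusted p = 0.74), amnion (2 rose and 3 fell of 11, camera adjusted p = 0.86), neuroectoderm (6 rose and 1 fell of 22, camera adjusted p = 0.059) and mesendoderm genes (4 rose and 9 fell of 19, 5 and 10 adjusted over the list alone, camera adjusted p = 0.088) were not called as lists. Among their members, TP63 (14 ± 2 against 1.61 ± 0.19 CPM, log2FC 3.12, adjusted p = 1.56e-07) and GATA6 (22.9 ± 1.4 against 6.35 ± 0.29 CPM, log2FC 1.85, adjusted p = 1.02e-06) rose and TBXT (1.18 ± 0.15 against 4.91 ± 0.96 CPM, log2FC −2.05, adjusted p = 0.00139) fell. OTX2 rose (10.8 ± 0.95 against 6.46 ± 0.76 CPM, log2FC 0.74, SE 0.13, adjusted p = 6.04e-05). In all, 4033 genes were higher and 4972 lower of 25063 tested, 1780 and 871 of them by at least 2-fold. This balance turned with RLE factors (4711 higher, 4093 lower) and DESeq2 (4069 higher, 3849 lower). The naive pluripotency genes were not called without TLSC WT replicate 2 or TLSC OTX2-KO replicate 2.

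The OTX2-KO effect in TLSC minus that in naive cells was tested as an interaction. The 8-cell embryo genes had the larger change in TLSC (14 positive and 0 negative of 35, camera adjusted p = 8.3e-19, estimated 0.0032). DPPA3 (5.08, SE 0.14, adjusted p = 1.2e-16) and KLF17 (2.69, SE 0.21, adjusted p = 2.52e-09) fell in naive cells and rose in TLSC, and TPRX1 (2, SE 0.26, adjusted p = 4.74e-06) also differed. DUX4 target genes had positive differences (6 positive and 0 negative of 23, camera adjusted p = 8.8e-16, estimated 0.0033). Members included ZSCAN4 (4.29, SE 0.73, adjusted p = 0.000114). FGF and ERK target genes had positive differences (9 positive and 0 negative of 16, 10 and 0 adjusted over the list alone, camera adjusted p = 4.7e-05, estimated 0.021). Members included SPRY4 (2.71, SE 0.32, adjusted p = 1.31e-06). In all, 2975 differences were positive and 4215 negative of 25063 genes tested, 1350 and 1630 of them at least 2-fold. The share of positive differences depended on scaling, 41.4% with TMM, 52.9% with RLE and 53% with DESeq2, as the median of all genes moved from −0.05 to 0.051 and 0.059. ZSCAN4 was not called without naive WT replicate 2.

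OTX2-OE and WT primed cells of set 2 were compared to ask the converse question. Doxycycline, by the labels in the OTX2-OE libraries alone, may have added to these changes. OTX2 itself stood at 26 ± 2.1 against 21.1 ± 2.3 CPM and was not called (adjusted p = 0.0897). p53 target genes fell (0 rose and 13 fell of 18, 0 and 15 adjusted over the list alone, camera adjusted p = 7.7e-16, estimated 0.0027). GDF15 (4.78 ± 0.29 against 15.6 ± 2.5 CPM, log2FC −1.7, SE 0.12, adjusted p = 1.83e-08), CDKN1A (14.3 ± 1.3 against 42 ± 1.8 CPM, log2FC −1.55, adjusted p = 8.29e-11) and BTG2 (4.69 ± 1.4 against 11.8 ± 1.8 CPM, log2FC −1.33, adjusted p = 1.36e-05) fell most among members of the list over 1 CPM. SLC16A3 (3.72 ± 0.45 against 15.4 ± 0.0063 CPM, log2FC −2.05, adjusted p = 2.58e-09), a lactate transporter, and TXNIP (19.4 ± 0.23 against 52.9 ± 2.6 CPM, log2FC −1.45, adjusted p = 8.29e-11), an inhibitor of thioredoxin, fell too. The DNA methylation machinery rose (2 rose and 0 fell of 13, 4 and 0 adjusted over the list alone, camera adjusted p = 0.0039, estimated 0.11). Members included UHRF1 (59 ± 2.1 against 39.8 ± 3.2 CPM, log2FC 0.57, adjusted p = 0.000477). Mitochondrially encoded genes fell (0 rose and 5 fell of 13, 0 and 8 adjusted over the list alone, camera adjusted p = 0.00062, estimated 0.44). In turn, the 8-cell embryo genes were not called as a list (0 rose and 0 fell of 30, camera adjusted p = 0.83), with 5 under 0.05 in edgeR before adjustment and 2 called by DESeq2. TPRX1 stood at 2.87 ± 0.65 against 2.96 ± 0.71 CPM. POU5F1 (2050 ± 130 against 2230 ± 10 CPM, adjusted p = 0.314) and SOX2 (259 ± 3.9 against 278 ± 0.039 CPM, adjusted p = 0.451) were not called. In all, 353 genes were higher and 489 lower of 24753 tested, 40 and 71 of them by at least 2-fold, with 1723 called when only the 2 groups were fitted. DESeq2 called 547 higher and 614 lower. The number called, 842, became 497 without primed OTX2-OE replicate 1, 345 without primed OTX2-OE replicate 2, 363 without primed WT replicate 1 and 251 without primed WT replicate 2. With only the 2 groups compared, OTX2 (adjusted p = 0.0441) and POU5F1 (0.0358) were called, OTX2 with DESeq2 too (0.0493).

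In naive cells of set 2, OTX2 rose with OTX2-OE (36.7 ± 0.48 against 25.5 ± 3.1 CPM, log2FC 0.52, SE 0.09, adjusted p = 0.000286). Mesendoderm genes rose (11 rose and 1 fell of 20, camera adjusted p = 1.7e-05, estimated 0.028). Members included LEFTY2 (3000 ± 50 against 801 ± 12 CPM, log2FC 1.9, SE 0.06, adjusted p = 3.06e-15), a Nodal antagonist, and WNT3 (23.2 ± 2.1 against 6.35 ± 0.39 CPM, log2FC 1.87, adjusted p = 1.58e-08). FGF and ERK target genes rose (7 rose and 0 fell of 16, 8 and 0 adjusted over the list alone, camera adjusted p = 3.9e-05, estimated 0.028). Members included SPRY4 (8.39 ± 0.87 against 2.07 ± 0.23 CPM, log2FC 2.03, adjusted p = 1.37e-09) and PHLDA1 (32.8 ± 0.17 against 15.5 ± 0.39 CPM, log2FC 1.08, adjusted p = 3.97e-09). Primed pluripotency genes rose (11 rose and 6 fell of 24, 11 and 7 adjusted over the list alone, camera adjusted p = 0.038, estimated 0.23), with ZIC2 (71 ± 4.3 against 20.6 ± 1.6 CPM, log2FC 1.79, adjusted p = 1.22e-11) rising and DNMT3B (1280 ± 30 against 2420 ± 28 CPM, log2FC −0.92, adjusted p = 2.87e-11) falling. Shared pluripotency genes fell (0 rose and 9 fell of 15, camera adjusted p = 3.9e-05, estimated 0.052). Among them were SOX2 (423 ± 18 against 658 ± 58 CPM, log2FC −0.64, adjusted p = 8.46e-08) and TDGF1 (887 ± 6.3 against 1530 ± 35 CPM, log2FC −0.79, adjusted p = 1.33e-09). p53 target genes rose (6 rose and 0 fell of 18, 7 and 0 adjusted over the list alone, camera adjusted p = 0.003, estimated 0.052). Members included GDF15 (13.9 ± 0.38 against 4.77 ± 0.53 CPM, log2FC 1.54, adjusted p = 1.01e-08). Naive pluripotency genes were not called as a list (8 rose and 7 fell of 26, 11 and 8 adjusted over the list alone, camera adjusted p = 0.9), where DPPA3 (95.6 ± 3.4 against 12.4 ± 1.4 CPM, log2FC 2.95, adjusted p = 1.87e-14) rose and DPPA5 (41.6 ± 1.1 against 97.5 ± 0.54 CPM, log2FC −1.23, adjusted p = 1.52e-07) and KHDC3L (2.12 ± 0.71 against 8.33 ± 1.3 CPM, log2FC −1.99, adjusted p = 7.97e-07) fell. TMPRSS4 (44.7 ± 4.8 against 0.295 ± 0.1 CPM, log2FC 7.24, adjusted p = 8.15e-15), a membrane serine protease, rose most of the named genes. In all, 2390 genes were higher and 2228 lower of 24753 tested, 698 and 483 of them by at least 2-fold. This balance turned with RLE factors (2299 higher, 2371 lower) and DESeq2 (2242 higher, 2374 lower). The number called, 4618, became 3018 without naive WT replicate 1 and 3064 without naive OTX2-OE replicate 1. The primed pluripotency genes were not called without naive WT replicate 1.

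In TLSC of set 2, OTX2 rose with OTX2-OE (200 ± 8.3 against 6.65 ± 0.2 CPM, log2FC 4.91, SE 0.11, adjusted p = 7.43e-18). Here the 8-cell embryo genes fell (2 rose and 14 fell of 30, 2 and 17 adjusted over the list alone, camera adjusted p = 4.9e-05, estimated 0.041). TPRX1 (47.4 ± 4.7 against 165 ± 5.9 CPM, log2FC −1.8, SE 0.1, adjusted p = 3.1e-11), DUXA (1.28 ± 0.18 against 3.51 ± 0.62 CPM, log2FC −1.46, adjusted p = 0.0181) and KLF17 (33 ± 0.63 against 73 ± 1 CPM, log2FC −1.15, adjusted p = 5.86e-07) fell. ZSCAN4 (2.48 ± 0.15 against 4.61 ± 0.12 CPM, adjusted p = 0.0852) and LEUTX (0.921 ± 0.03 against 2.09 ± 0.57 CPM, adjusted p = 0.127) were not called. DPPA3 (222 ± 20 against 104 ± 7.5 CPM, log2FC 1.1, adjusted p = 3.98e-09) rose. DUX4 target genes fell (0 rose and 7 fell of 18, 0 and 10 adjusted over the list alone, camera adjusted p = 6.1e-05, estimated 0.19). Members included CCNA1 (970 ± 42 against 3040 ± 120 CPM, log2FC −1.65, adjusted p = 3e-12), the germ line cyclin. Shared pluripotency genes fell (1 rose and 13 fell of 15, 1 and 14 adjusted over the list alone, camera adjusted p = 1.7e-08, estimated 0.03). Among them were NANOG (128 ± 0.75 against 247 ± 0.76 CPM, log2FC −0.94, adjusted p = 4.2e-11) and POU5F1 (781 ± 86 against 1190 ± 1.9 CPM, log2FC −0.61, adjusted p = 9.07e-08). The FGF and ERK target genes rose (8 rose and 2 fell of 16, 9 and 2 adjusted over the list alone, camera adjusted p = 5.2e-05, estimated 0.03). Members included DUSP4 (18.3 ± 3.1 against 2.5 ± 0.17 CPM, log2FC 2.88, adjusted p = 7.85e-12). The naive list was not called (4 rose and 16 fell of 26, camera adjusted p = 0.084), though FGF4 (89.6 ± 3.7 against 282 ± 5.7 CPM, log2FC −1.65, adjusted p = 6.42e-14) fell. Of primed genes ZIC2 (18.9 ± 0.003 against 7.17 ± 1.6 CPM, log2FC 1.4, adjusted p = 2.38e-09) rose. DPRX (11.4 ± 0.9 against 0.412 ± 0.13 CPM, log2FC 4.78, adjusted p = 3.73e-09), a PRD-like homeobox gene, rose too. In all, 2766 genes were higher and 4107 lower of 24753 tested, 623 and 916 of them by at least 2-fold. DUXA was not called when any TLSC WT or OTX2-OE library was left out. ZSCAN4 and LEUTX were called with only the 2 groups compared (adjusted p = 0.00879 and 0.0254).

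The OTX2-OE effect in TLSC minus that in naive cells was tested as an interaction. OTX2 RNA itself rose more in TLSC than in naive cells (log2FC 4.91 and 0.52, log2 difference 4.39, SE 0.14, adjusted p = 1.83e-14). The effect of the state therefore cannot be told apart from that of this larger rise. Genes of the 8-cell embryo had negative differences (0 positive and 7 negative of 30, camera adjusted p = 5.3e-06, estimated 0.04). Members included DPPA3 (−1.85, SE 0.13, adjusted p = 4.24e-09). Other members, such as DUXA and LEUTX with 0 counts in both naive groups, could not fall in naive cells. Nodal and TGF-beta target genes had negative differences (0 positive and 12 negative of 14, 0 and 13 adjusted over the list alone, camera adjusted p = 2.4e-09, estimated 0.04). Stress response genes had negative differences (0 positive and 10 negative of 17, 0 and 12 adjusted over the list alone, camera adjusted p = 0.00016, estimated 0.18). Members included DDIT3 (−2.15, SE 0.19, adjusted p = 4.98e-08). In all, 1579 differences were positive and 2846 negative of 24753 genes tested, 364 and 779 of them at least 2-fold.

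Genes called with OTX2-KO in set 1 were matched to those called with OTX2-OE in set 2, which shares no library with it. In primed cells 440 genes changed in opposite directions, against 71.8 from n1 × n2 / N, and 32 in the same direction against 69.6 (Fisher exact p = 5.56e-140 for higher with OTX2-KO and lower with OTX2-OE, Pearson −0.214 and Spearman −0.289 across genes). GDF15, CDKN1A and BTG2 were among the 260 of the former kind. OTX2 RNA rose with OTX2-KO in primed cells and was not called with OTX2-OE, where doxycycline may have acted. Loss against gain of OTX2 was thus not tested there. In naive cells the counts were 1616 opposite against 901 and 935 in the same direction against 902 (Fisher exact p = 1.58e-92 for higher with OTX2-KO and lower with OTX2-OE, Pearson −0.0882, Spearman −0.121); for example DPPA3 and ZIC2 fell with OTX2-KO and rose with OTX2-OE. In TLSC both kinds exceeded n1 × n2 / N, with 1861 opposite against 1240 and 1879 in the same direction against 1310 (Fisher exact p = 8.38e-69 for higher with OTX2-KO and lower with OTX2-OE, 2.57e-69 for both lower, Pearson 0.0364, Spearman 0.0144). There TPRX1, DUXA and KLF17 rose with OTX2-KO and fell with OTX2-OE, and DPPA3 rose with both.

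Set 3 compared OTX2-KO and WT TLSC again, beside DUX4-OE. The 8-cell embryo genes rose (27 rose and 0 fell of 41, 30 and 0 adjusted over the list alone, camera adjusted p = 5.9e-15, estimated 0.28). TPRX1 (81.4 ± 9.2 against 42.4 ± 13 CPM, log2FC 0.94, SE 0.15, adjusted p = 0.000119), ZSCAN4 (4.88 ± 0.61 against 0.62 ± 0.0036 CPM, log2FC 2.97, adjusted p = 4.72e-08), DUXA (4.88 ± 0.62 against 0.542 ± 0.24 CPM, log2FC 3.16, adjusted p = 3.01e-08), LEUTX (2.19 ± 0.55 against 0.372 ± 0.18 CPM, log2FC 2.54, adjusted p = 1.17e-05), KLF17 (99.5 ± 3 against 65.1 ± 5.4 CPM, log2FC 0.61, adjusted p = 0.000352) and DPPA3 (144 ± 26 against 65.3 ± 8.4 CPM, log2FC 1.14, adjusted p = 1.3e-06) were among them. DUX4 target genes rose (17 rose and 0 fell of 26, 19 and 0 adjusted over the list alone, camera adjusted p = 1.7e-11, estimated 0.14). DPPA5 (871 ± 86 against 523 ± 92 CPM, log2FC 0.74, adjusted p = 0.000173) of the naive list and POU5F1 (2930 ± 290 against 1980 ± 340 CPM, log2FC 0.57, adjusted p = 0.0018) rose too. Primed pluripotency genes fell (0 rose and 15 fell of 24, 0 and 17 adjusted over the list alone, camera adjusted p = 2.6e-07, estimated 0.14). Members included ZIC2 (2.53 ± 0.53 against 6.66 ± 0.79 CPM, log2FC −1.39, adjusted p = 0.000162). Mesendoderm genes fell (1 rose and 6 fell of 20, camera adjusted p = 0.0069, estimated 0.36). Among them was TBXT (1.89 ± 0.34 against 9.56 ± 0.54 CPM, log2FC −2.33, adjusted p = 7.63e-09), the brachyury gene. Stress response genes rose (7 rose and 2 fell of 17, 8 and 2 adjusted over the list alone, camera adjusted p = 0.0025, estimated 0.41). Members included HMOX1 (110 ± 6 against 41.8 ± 2.9 CPM, log2FC 1.4, adjusted p = 2.03e-08). OTX2 stood at 6.81 ± 1.2 against 5.61 ± 0.98 CPM (adjusted p = 0.355). In all, 2470 genes were higher and 2009 lower of 21722 tested, 419 and 413 of them by at least 2-fold. Of genes tested in sets 1 and 3, 1803 changed in the same direction with OTX2-KO in TLSC against 894 from n1 × n2 / N, and 799 in opposite directions against 920 (Fisher exact p = 2.53e-127 for both higher, Pearson 0.257, Spearman 0.198 across genes). The number called, 4479, became 2350 without TLSC OTX2-KO replicate 1.

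DUX4-OE and WT TLSC were compared to describe the changes in cells labelled DUX4-OE. The 8-cell embryo genes rose (34 rose and 1 fell of 41, 35 and 3 adjusted over the list alone, camera adjusted p = 9.7e-16, estimated 0.22). DUX4 target genes rose (23 rose and 0 fell of 26, 24 and 0 adjusted over the list alone, camera adjusted p = 1.1e-14, estimated 0.17). ZSCAN4 (12.7 ± 0.75 against 0.62 ± 0.0036 CPM, log2FC 4.35, SE 0.24, adjusted p = 3.84e-12), DUXA (8.31 ± 0.04 against 0.542 ± 0.24 CPM, log2FC 3.93, adjusted p = 4.69e-11) and LEUTX (6.19 ± 0.28 against 0.372 ± 0.18 CPM, log2FC 4.04, adjusted p = 5.12e-10) rose, as did TRIM43 (4.19 ± 0.05 against 0 ± 0 CPM, at least 90.1-fold higher, adjusted p = 4.61e-11). TPRX1 (67.5 ± 8.3 against 42.4 ± 13 CPM, log2FC 0.67, adjusted p = 0.00126) and DPPA3 (104 ± 1.9 against 65.3 ± 8.4 CPM, log2FC 0.67, adjusted p = 0.000208) rose less. KLF17 stood at 66.5 ± 0.26 against 65.1 ± 5.4 CPM (adjusted p = 0.868). Mesendoderm genes rose (13 rose and 3 fell of 20, camera adjusted p = 0.00015, estimated 0.22). Members included TBXT (112 ± 0.89 against 9.56 ± 0.54 CPM, log2FC 3.56, adjusted p = 3.05e-14) and MIXL1 (50.5 ± 0.9 against 10 ± 0.4 CPM, log2FC 2.33, adjusted p = 1.07e-11). FGF and ERK target genes rose (12 rose and 0 fell of 16, camera adjusted p = 8.6e-05, estimated 0.28). Trophoblast genes rose (12 rose and 1 fell of 21, camera adjusted p = 0.003, estimated 0.41). Among them was CDX2 (13.7 ± 0.88 against 1.81 ± 0.19 CPM, log2FC 2.92, adjusted p = 7.75e-09). GATA6 (13.2 ± 0.75 against 3.36 ± 1.5 CPM, log2FC 1.97, adjusted p = 7.33e-07) rose. Shared pluripotency genes fell (2 rose and 12 fell of 15, camera adjusted p = 0.0012, estimated 0.18). Members included POU5F1 (1070 ± 33 against 1980 ± 340 CPM, log2FC −0.88, adjusted p = 6.22e-06) and TDGF1 (101 ± 4.3 against 387 ± 12 CPM, log2FC −1.93, adjusted p = 1.01e-11). NDUFA4L2 (2.16 ± 0.61 against 44.9 ± 0.9 CPM, log2FC −4.38, adjusted p = 3.79e-14), a nuclear gene induced in hypoxia, and DAZL (2.06 ± 0.005 against 24 ± 3 CPM, log2FC −3.54, adjusted p = 5.85e-11), a germ cell RNA-binding protein, fell. OTX2 stood at 7.54 ± 0.56 against 5.61 ± 0.98 CPM (adjusted p = 0.0951). In all, 3989 genes were higher and 3684 lower of 21722 tested, 1450 and 1310 of them by at least 2-fold. The number called, 7673, became 4963 without TLSC DUX4-OE replicate 1 and 4934 without TLSC DUX4-OE replicate 2. OTX2 was called without TLSC WT replicate 1.

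In OTX2-KO TLSC, adding DUX4-OE raised the 8-cell embryo genes (40 rose and 0 fell of 41, camera adjusted p = 4.1e-17, estimated 0.2). TPRX1 (247 ± 13 against 81.4 ± 9.2 CPM, log2FC 1.6, SE 0.15, adjusted p = 1.16e-08), ZSCAN4 (45.4 ± 11 against 4.88 ± 0.61 CPM, log2FC 3.22, adjusted p = 4.39e-12), KLF17 (192 ± 11 against 99.5 ± 3 CPM, log2FC 0.95, adjusted p = 2.23e-07) and DPPA3 (416 ± 31 against 144 ± 26 CPM, log2FC 1.53, adjusted p = 1.7e-09) rose. DUX4 target genes rose (26 rose and 0 fell of 26, camera adjusted p = 3.1e-13, estimated 0.2). FGF and ERK target genes rose (15 rose and 0 fell of 16, 16 and 0 adjusted over the list alone, camera adjusted p = 1.1e-07, estimated 0.2). Members included DUSP4 (10.3 ± 0.23 against 0.509 ± 0.0098 CPM, log2FC 4.33, adjusted p = 1.85e-08). Primed pluripotency genes rose (13 rose and 4 fell of 24, 14 and 4 adjusted over the list alone, camera adjusted p = 0.019, estimated 0.29). Among them was ZIC2 (10.2 ± 2.3 against 2.53 ± 0.53 CPM, log2FC 2.01, adjusted p = 1.84e-07). Trophoblast genes rose (16 rose and 1 fell of 21, camera adjusted p = 0.00035, estimated 0.29). NDUFA4L2 (0.98 ± 0.24 against 60.2 ± 3.6 CPM, log2FC −5.92, adjusted p = 6.6e-16) and FAM162A (24.7 ± 2.8 against 310 ± 4.6 CPM, log2FC −3.65, adjusted p = 7.86e-16), genes induced in hypoxia, fell. POU5F1 (1290 ± 120 against 2930 ± 290 CPM, log2FC −1.19, adjusted p = 5.45e-08) fell too. OTX2 rose (12.2 ± 0.44 against 6.81 ± 1.2 CPM, log2FC 0.84, SE 0.19, adjusted p = 0.000907). In all, 5184 genes were higher and 4747 lower of 21722 tested, 2318 and 1838 of them by at least 2-fold. The primed pluripotency genes were not called without TLSC OTX2-KO replicate 1.

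DUX4-OE cells with and without OTX2-KO were compared to ask what the knockout added. In turn, the 8-cell embryo genes rose (32 rose and 0 fell of 41, 34 and 0 adjusted over the list alone, camera adjusted p = 1.5e-16, estimated 0.23). TPRX1 (247 ± 13 against 67.5 ± 8.3 CPM, log2FC 1.87, SE 0.15, adjusted p = 1.88e-09), ZSCAN4 (45.4 ± 11 against 12.7 ± 0.75 CPM, log2FC 1.84, adjusted p = 9.93e-09), DUXA (32.2 ± 4.4 against 8.31 ± 0.04 CPM, log2FC 1.96, adjusted p = 1.08e-08), KLF17 (192 ± 11 against 66.5 ± 0.26 CPM, log2FC 1.53, adjusted p = 3.17e-10) and DPPA3 (416 ± 31 against 104 ± 1.9 CPM, log2FC 2, adjusted p = 3.94e-11) rose. Oocyte and germ cell genes rose (13 rose and 0 fell of 27, camera adjusted p = 1.3e-05, estimated 0.12). Members included SYCP1 (22.5 ± 1.7 against 2.28 ± 0.13 CPM, log2FC 3.3, adjusted p = 1.88e-09), a component of the synaptonemal complex. Stress response genes rose (15 rose and 0 fell of 17, camera adjusted p = 6.7e-07, estimated 0.23). Mesendoderm genes fell (2 rose and 10 fell of 20, 3 and 10 adjusted over the list alone, camera adjusted p = 0.00033, estimated 0.23). Members included TBXT (9.94 ± 0.27 against 112 ± 0.89 CPM, log2FC −3.5, adjusted p = 1.84e-14) and MIXL1 (16.8 ± 0.87 against 50.5 ± 0.9 CPM, log2FC −1.59, adjusted p = 2.75e-09). FOXA2 (1.25 ± 0.4 against 22.1 ± 2 CPM, log2FC −4.12, adjusted p = 3.05e-11) and CDX2 (3.42 ± 0.73 against 13.7 ± 0.88 CPM, log2FC −2.01, adjusted p = 7.61e-07) fell as well. POU5F1 stood at 1290 ± 120 against 1070 ± 33 CPM (adjusted p = 0.108). In all, 3679 genes were higher and 3408 lower of 21722 tested, 1389 and 1081 of them by at least 2-fold. The number called, 7087, became 4523 without TLSC DUX4-OE replicate 1 and 4453 without TLSC DUX4-OE replicate 2. POU5F1 was called with only the 2 groups compared (adjusted p = 0.0139).

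Whether DUX4-OE acted differently in OTX2-KO and WT cells was tested as an interaction. Summed DUX4 and DUX4L counts were higher with DUX4-OE in OTX2-KO cells (64 and 68 against 28 and 23) but not in WT. An effect of OTX2-KO thus cannot be told apart from a larger DUX4 dose. Here the 8-cell embryo genes were not called as a list (7 positive and 4 negative of 41, 8 and 4 adjusted over the list alone, camera adjusted p = 0.11). DUX4 target genes were not called as a list (1 positive and 3 negative of 26, 2 and 3 adjusted over the list alone, camera adjusted p = 0.64). TPRX1 (0.93, SE 0.21, adjusted p = 0.00599), KLF17 (0.92, SE 0.16, adjusted p = 0.000525) and DPPA3 (0.86, SE 0.18, adjusted p = 0.00293) had the larger rise in OTX2-KO cells, and DUXA (−1.21, SE 0.33, adjusted p = 0.0209) and ZSCAN4 (−1.13, SE 0.32, adjusted p = 0.025) the larger rise in WT, as had TRIM43 and TRIM43B, at or near 0 in WT (adjusted p = 0.0111 and 0.00818). Primed pluripotency genes had positive differences (8 positive and 0 negative of 24, 12 and 0 adjusted over the list alone, camera adjusted p = 0.00042, estimated 0.28). Among them was ZIC2 (1.83, SE 0.31, adjusted p = 0.000547). FGF and ERK target genes had positive differences (8 positive and 0 negative of 16, 10 and 0 adjusted over the list alone, camera adjusted p = 0.00039, estimated 0.36). In all, 1214 differences were positive and 1168 negative of 21722 genes tested, 509 and 391 of them at least 2-fold. This balance turned with RLE factors (1151 higher, 1179 lower) and DESeq2 (1297 higher, 1367 lower). Between the DUX4-OE effects in WT and in OTX2-KO cells 5373 genes changed in the same direction against 1760 from n1 × n2 / N, and 180 in opposite directions (Fisher exact p again under the range of double precision; Pearson 0.619, Spearman 0.628 across genes). The number called, 2382, became 1073 without TLSC DUX4-OE replicate 1, 1171 without TLSC DUX4-OE replicate 2 and 1272 without TLSC DUX4-OE OTX2-KO replicate 2. DUXA was not called without replicate 2 of TLSC WT, OTX2-KO or DUX4-OE OTX2-KO. ZSCAN4 was not called without TLSC WT replicate 1 or 2, DUX4-OE replicate 2, OTX2-KO replicate 1 or DUX4-OE OTX2-KO replicate 2. TRIM43 was not called without TLSC WT replicate 1 or 2, nor TRIM43B without TLSC WT replicate 2. Genes of the 8-cell embryo were called without TLSC WT replicate 2, TLSC OTX2-KO replicate 1 or TLSC DUX4-OE OTX2-KO replicate 2.

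**Figure D4:**
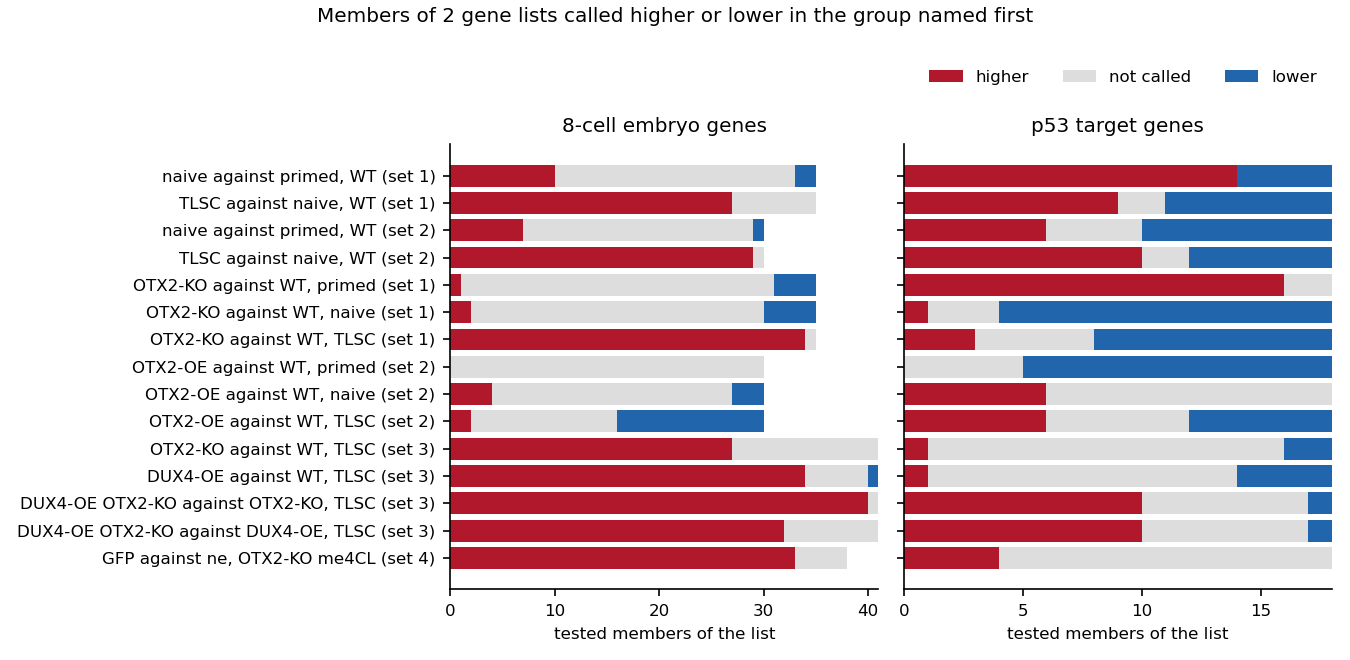
Number of tested members of the 8-cell embryo and p53 target lists that were called higher (red), called lower (blue) or not called (grey) in the group named first in each of the 15 comparisons. All 18 p53 genes were tested in each comparison, and the 8-cell bar has no blue part in TLSC with OTX2-KO of set 1, where 34 of 35 rose.

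GFP and ne libraries of OTX2-KO cells in me4CL were compared in set 4. The labels name the libraries GFP and ne without saying what drives the reporter. Genes of the 8-cell embryo rose in GFP libraries (33 rose and 0 fell of 38, 34 and 0 adjusted over the list alone, camera adjusted p = 2.5e-29, estimated 0.01). ZSCAN4 (90.8 ± 46 against 3.35 ± 1.1 CPM, log2FC 4.75, SE 0.36, adjusted p = 4.74e-06), LEUTX (112 ± 7.7 against 7.17 ± 1.5 CPM, log2FC 3.96, adjusted p = 5.63e-08), DUXA (135 ± 11 against 14.8 ± 0.75 CPM, log2FC 3.19, adjusted p = 5.63e-08), TPRX1 (51.7 ± 14 against 12.8 ± 1.8 CPM, log2FC 2.02, adjusted p = 3.65e-05), DPPA3 (1870 ± 130 against 496 ± 24 CPM, log2FC 1.91, adjusted p = 1.37e-05) and KLF17 (211 ± 28 against 104 ± 8 CPM, log2FC 1.02, adjusted p = 0.000761) rose. DUX4 target genes rose (24 rose and 0 fell of 24, camera adjusted p = 3.3e-26, estimated 0.016). Members included MBD3L2 (118 ± 4.5 against 2.86 ± 0.36 CPM, log2FC 5.36, adjusted p = 3.24e-09). Stress response genes rose (11 rose and 0 fell of 17, 12 and 1 adjusted over the list alone, camera adjusted p = 1.2e-05, estimated 0.073). Members included HSPA1A (262 ± 9.5 against 69.3 ± 2.3 CPM, log2FC 1.92, adjusted p = 3.11e-06). Nodal and TGF-beta target genes fell (0 rose and 7 fell of 14, 0 and 8 adjusted over the list alone, camera adjusted p = 0.00041, estimated 0.12). Among them were LEFTY2 (385 ± 71 against 1110 ± 76 CPM, log2FC −1.53, adjusted p = 0.000142) and TDGF1 (120 ± 5.8 against 302 ± 26 CPM, log2FC −1.34, adjusted p = 7.67e-05). Shared pluripotency genes fell (1 rose and 7 fell of 15, 1 and 9 adjusted over the list alone, camera adjusted p = 0.0022, estimated 0.53), with NANOG (64.4 ± 20 against 131 ± 23 CPM, log2FC −1.03, adjusted p = 0.00781) falling and SOX2 (73.9 ± 17 against 36.4 ± 1.2 CPM, log2FC 1.02, adjusted p = 0.00151) rising. POU5F1 stood at 726 ± 190 against 1060 ± 220 CPM (adjusted p = 0.109). Neuroectoderm genes rose (10 rose and 2 fell of 23, camera adjusted p = 0.0022, estimated 0.29). Members included DCX (34.4 ± 8.2 against 6.79 ± 1.3 CPM, log2FC 2.34, adjusted p = 1.5e-05). GATA6 (22.8 ± 2.3 against 5.55 ± 1.2 CPM, log2FC 2.04, adjusted p = 1.5e-05) and GATA3 (13.9 ± 1.4 against 6.73 ± 1.1 CPM, log2FC 1.04, adjusted p = 0.00128) rose and TBXT (1.69 ± 0.72 against 7.17 ± 0.43 CPM, log2FC −2.08, adjusted p = 0.000239) fell, while hypoblast (camera adjusted p = 0.71), trophoblast (0.45), amnion (0.078) and mesendoderm genes (0.51) were not called as lists. OTX2 rose (30.6 ± 5.1 against 18.6 ± 1.5 CPM, log2FC 0.72, SE 0.15, adjusted p = 0.00703). In all, 2301 genes were higher and 1941 lower of 22087 tested, 1141 and 501 of them by at least 2-fold. NANOG was not called without OTX2-KO ne replicate 3 (adjusted p = 0.0564). POU5F1 was called with no low-count filter (adjusted p = 0.0239) or with replicate 3 of both groups left out (9.85e-06). The amnion genes were called with replicate 3 of both groups left out (adjusted p = 0.021).

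Mitochondrially encoded genes fell (0 rose and 7 fell of 13, 0 and 11 adjusted over the list alone, camera adjusted p = 0.00014, estimated 0.53) in set 4. They took 4.277% ± 2.371 of counts in GFP libraries and 8.523% ± 0.8411 in ne libraries (SD, n = 3), with 1.55% in GFP replicate 3. Chi-square per gene was 128 and 121 between GFP replicate 3 and the other GFP libraries and 8.05 to 23.9 within the rest. Leaving out replicate 3 of both groups, chosen after seeing the data, gave 6967 called genes. Of genes tested in sets 1 and 4, 2013 changed in the same direction in GFP libraries and with OTX2-KO in TLSC of set 1 against 837 from n1 × n2 / N, and 308 in opposite directions against 847 (Fisher exact p = 3.53e-278 for both higher, Pearson 0.402, Spearman 0.318 across genes). The number called, 4242, became 6740 without OTX2-KO GFP replicate 3, 2181 without OTX2-KO ne replicate 1, 2328 without OTX2-KO ne replicate 2 and 2098 without OTX2-KO ne replicate 3.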

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

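The tests of the p53 and mitochondrial patterns were chosen after their results were seen, and the splits of set 4 were planned.

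The OTX2-KO effect on p53 target genes differed between naive and primed cells (interaction camera adjusted p = 8.6e-14, adjusted p = 0.033 with an estimated correlation), rising in primed and falling in naive cells, where the call was lost with an estimated correlation (adjusted p = 0.16). The list lay at −1.26 from the median of all genes (quartiles −1.91 to −0.87), which argues against scaling, since a factor moves all genes of a library alike, and the fits that each left 1 library out gave 1.1e-14 to 1.8e-13, which argues against 1 library. A difference between the OTX2-KO and WT lines other than OTX2 may account for it, because only 1 set holds OTX2-KO primed libraries, and the design cannot part it from OTX2. A candidate explanation is that OTX2 acts on these genes in opposite directions in the 2 states, but OTX2 RNA itself rose with OTX2-KO in primed cells (log2 fold change 1.64) and fell in naive cells (−0.34, not called in some alternatives), so 1 direction in both states stays open if that RNA yields working protein. The OTX2-OE effect, naive minus primed, moved the list the other way (camera p = 6.1e-12, p = 0.00041 with an estimated correlation), but OTX2 RNA in primed OTX2-OE cells was called higher only with DESeq2 (adjusted p = 0.0493) or a fit of only the 2 groups (0.0441), and doxycycline, by the labels in those libraries alone, may have acted too, which keeps this open.

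Mitochondrially encoded genes were lower in GFP libraries of set 4, with a median log2 fold change of −1.07 (camera adjusted p = 0.00014), but the call was lost with an estimated correlation (adjusted p = 0.53). GFP replicate 3 alone could not be the whole cause, since the median was −0.74 without that library (camera adjusted p = 1.7e-05). The list lay at −1.07 from the median of all genes (quartiles −1.15 to −0.99). This again restates the camera call by which the list was chosen, so it does not test scaling. No biological explanation was tested. The number of genes called between GFP and ne libraries was 4242, and the other 9 splits of these libraries gave at most 0 in edgeR (at most 760 at an unadjusted p under 0.05, and 0 in DESeq2). The real count was reached in 1 of 10 splits, which are too few for a share under 0.05.

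The other values come from tests of a difference between effects. Among called differences of the OTX2-KO effect, naive minus primed, 1109 genes were called in opposite directions in the 2 states. OTX2 (−1.98), SUSD2 (−2.05) and POU5F1 (−1.06) were among them, as log2 differences. For TLSC minus naive, 1139 genes were called in opposite directions, and OTX2 (1.08), KLF17 (2.69), DPPA3 (5.08), NANOG (0.89), ZIC2 (2.8), DNMT3L (1.28) and DPPA5 (−0.8) were among them. The lists that differed there were 8-cell embryo genes (camera adjusted p = 8.3e-19), DUX4 target genes (8.8e-16) and FGF and ERK target genes (4.7e-05), with adjusted p of 0.0032, 0.0033 and 0.021 with an estimated correlation. The OTX2-OE effect, TLSC minus naive, put 557 genes in opposite directions, with 8-cell embryo genes (camera adjusted p = 5.3e-06) and Nodal and TGF-beta target genes (2.4e-09), each with an adjusted p of 0.04 with an estimated correlation. The DUX4-OE effect, OTX2-KO minus WT, put 180 genes in opposite directions. The GFP entry of the set 4 table, used in no comparison, averaged 46.26 CPM in GFP libraries and 7.067 CPM in ne libraries, a ratio of 6.55 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give).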

How the results depend on the processing

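The crossed replicate block and the fit without replicate 3 of both groups of set 4 were chosen after the results were seen. The other alternatives were set before the data were examined. In the simulated data small changes were called less often, as the recovery at 1.5-fold shows, and depth itself was not varied. Each group holds 2 or 3 libraries, so a fit without 1 library often rests on a single library of a group. Of the 1961 results of named genes, 1535 had the same call and direction in every alternative run, and of 380 list tests 246 did. Calls of named genes lost and gained numbered 68 and 15 with DESeq2, 20 and 2 with RLE factors, 36 and 13 with no low-count filter, 34 and 17 with only the 2 groups compared, 40 and 9 with the replicate block, and 997 and 37 over all fits without 1 library. Except for the values that follow, the total counts of each comparison, interaction and overlap stayed within 1.5 times those reported under the alternatives run.

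Requiring a log2 fold change of at least 1 in size left, by its construction, fewer calls: 9864 for naive against primed in set 1, 7068 for TLSC against naive in set 1, 6349 for naive against primed in set 2, 7766 for TLSC against naive in set 2, 1004 for OTX2-KO in primed cells, 2844 for OTX2-KO in naive cells, 2651 for OTX2-KO in TLSC of set 1, 111 for OTX2-OE in primed cells, 1181 for OTX2-OE in naive cells, 1539 for OTX2-OE in TLSC, 832 for OTX2-KO in TLSC of set 3, 2760 for DUX4-OE in WT, 4156 for DUX4-OE in OTX2-KO cells, 2470 for OTX2-KO in DUX4-OE cells, 1642 for GFP against ne, 2667 for the OTX2-KO interaction of naive and primed cells, 2980 for the OTX2-KO interaction of TLSC and naive cells, 1143 for the OTX2-OE interaction and 900 for the DUX4-OE interaction. The overlaps were then 29 in primed cells, 236 in naive cells, 256 in TLSC, 300 between TLSC of sets 1 and 3, 1592 between the DUX4-OE effects, 534 between sets 1 and 4 and 3933 between TLSC against naive of sets 1 and 2. Fitting only the 2 groups gave 7510 calls for OTX2-KO in primed cells and 1723 for OTX2-OE in primed cells, and the cause was not tested. With an estimated correlation 30 list tests were called in place of 155. Without replicate 3 of both groups, GFP against ne called 6967 genes.

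With 1 library left out, the number of genes called ran from 1690 to 2722 for OTX2-KO in primed cells (3967 with all libraries), 251 to 497 for OTX2-OE in primed cells (842 with all libraries), 3018 to 3401 for OTX2-OE in naive cells (4618 with all libraries), 2350 to 4381 for OTX2-KO in TLSC of set 3 (4479 with all libraries), 4934 to 6912 for DUX4-OE in WT (7673 with all libraries), 4453 to 5799 for OTX2-KO in DUX4-OE cells (7087 with all libraries), 2098 to 6740 for GFP against ne (4242 with all libraries) and 1073 to 2727 for the DUX4-OE interaction (2382 with all libraries). Fewer libraries lower the power by construction, and the cause of the rises above the number with all libraries was not tested. Some named results changed direction and 1 went to 0, for causes that were not tested. Naive pluripotency genes for OTX2-OE in primed cells turned to lower without primed OTX2-OE replicate 2 (adjusted p = 0.02, with 0.0054 to 0.62 over the libraries left out and 0.83 with all). CDX2 for naive against primed in set 1 went to 0 without primed WT replicate 2 (adjusted p = 1, from −5.32, with −6.27 to 0 over the libraries left out). RMRP for TLSC against naive in set 1 turned to 2.39 without naive WT replicate 1 (adjusted p = 0.211, from −4.08, with −7.76 to 2.39 over the libraries left out). CDX2 for naive against primed in set 2 turned to 3.31 without primed WT replicate 1 (adjusted p = 0.364, from −3.02, with −6.35 to 3.31 over the libraries left out). RMRP for OTX2-KO in naive cells turned to 3.55 without naive WT replicate 1 (adjusted p = 0.0457, from −2.92, with −3.89 to 3.55 over the libraries left out). ALPG for OTX2-OE in primed cells turned to −1.13 without primed OTX2-OE replicate 2 (adjusted p = 0.00121, from 1.12, with −1.13 to 1.96 over the libraries left out). CCDC26 for the OTX2-KO interaction of TLSC and naive cells turned to −4.96 without naive WT replicate 1 (adjusted p = 0.413, from 5.05, with −4.96 to 7.08 over the libraries left out).

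Deviations of libraries with the same replicate number correlated at −0.08 to 0.15 in sets 1 to 3, except −0.25 for OTX2-KO in TLSC of set 1, and at −0.19, 0.14 and −0.1 in set 4, so the numbers do not pair the samples. The replicate block gave 513 calls for OTX2-OE in primed cells and an overlap of 291 there, and a crossed block gave 9673 calls for OTX2-KO in TLSC of set 1.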

Other observations

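The test of hypoxia targets was written before its result was seen, after NDUFA4L2, P4HA1 and FAM162A had been seen to fall. Other targets of hypoxia-inducible factors, a list that left out these 3 genes, fell with DUX4-OE in TLSC of set 3. In OTX2-KO cells 7 rose and 19 fell of 28 (median log2 fold change −1.13, camera p = 8e-05, p = 0.031 with an estimated correlation), and in WT cells 3 rose and 22 fell (median −0.95, camera p = 2e-08, p = 0.0095 with an estimated correlation). With OTX2-KO 14 rose and 1 fell against WT (median 0.36, p = 0.018 with an estimated correlation) and 12 rose and 3 fell in DUX4-OE cells (median 0.42, p = 0.038), in contrasts that share libraries with the first 2 and are no separate evidence. Lower activity of hypoxia-inducible factors with DUX4-OE may therefore account for the fall of the 3 genes. Oxygen, cell density and the day of culture were not given by the labels and stay open.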
